A study of Mus musculus with 9 samples.

How the data were processed

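Libraries were made with an mRNA kit from 2 µg of total RNA of BV2 cells, per the labels' protocols. Cells were exposed to siRNA and RNAiMAX for 24 h and kept in fresh medium for another 24 h. Each of 9 samples was assigned to control, siRNA 644 or siRNA 878 from its title, with 3 replicates per group.

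The deposited table held estimated counts per gene, which the authors did not round: 37.4% of nonzero values were not whole within 1e-09. It also held FPKM values made by the authors, and the authors' own log2 fold changes and DESeq2 q-values per the file headers. The submitters' processing notes name Bowtie2 2.4.5, DESeq2 1.34.0 and the build mm39. The counting tool, the way gene length was set for FPKM, the strand setting and the annotation are not given in the sources used here, so genes with near-identical copies or antisense partners carry that uncertainty. The table has 16399 genes, none on the mitochondrial chromosome. A further 9 per-sample columns of TPM, 9 columns of group averages and 3 columns of unadjusted p-values were not used.

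Gene positions are as the table gives them, counted from 1. Of 16348 genes matched by NCBI gene ID, 12052 (73.7%) had the same chromosome, start and end in RefSeq of GRCm38.p6. The processing notes name mm39, so the build of the coordinates is open and positions should be read as those of the table.

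The estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 11740 genes holding at least 99.96% of counts in each library. Library sizes were 19362486 to 20224998 and TMM factors 0.898 to 1.04. The test was edgeR 4.0.16's quasi-likelihood F-test in R 4.3.3, fitted over all 9 samples with group as the only term, so the groups shared 1 estimate of spread. The contrasts were 644 against control, 878 against control, 878 against 644 and the mean of both siRNAs against control. P-values were adjusted by Benjamini-Hochberg and called under 0.05. The SE of a log2 fold change was its size divided by the square root of F. The common dispersion corresponded to a biological coefficient of variation of 14.9%. Intervals and floors (95%, 3 counts) cover counting error only.

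Gene lists, tests, the rule for named genes and most alternatives were set before the data were examined. The 20 lists cover dolichol synthesis and N-glycosylation, iron, cholesterol biosynthesis and uptake, cholesterol efflux, lysosome, ER chaperones, integrated stress response, NF-kB and cytokines, interferon response, NRF2 targets with ferroptosis genes, homeostatic and disease-associated microglia markers, S phase, G2 and mitosis, p53 targets, glycolysis and hypoxia, oxidative phosphorylation, mitochondrial mRNAs, ribosomal proteins and markers of other cell types. The mitochondrial list had no gene in the table, so 19 were tested. Lists were tested by camera (preset correlation 0.01) and again with an estimated correlation and with fry.

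Genes were named by these rules. Nus1, Lcn2 and Slc22a17 were named in each comparison. The 10 genes with the largest smaller change in both siRNAs were named per direction, among genes called for both with average log2 CPM of at least 1 and an established symbol. For each siRNA, up to 5 genes per direction were named among those also called between the siRNAs. Up to 4 called members were named of a called list and up to 2 of another list. Some genes that met these rules are not reported here.

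On simulated data with 200 changed genes among 11740, edgeR recovered 38.8%, 85.1% and 98.5% of genes changed 1.5-, 2- and 4-fold for 644 against control. For 878 against control it recovered 35.8%, 76.1% and 93.9%, for 878 against 644 it recovered 23.9%, 70.1% and 93.9%, and for the averaged comparison 38.8%, 80.6% and 98.5%. Lists of 30 genes shifted 1.5-fold were called in each simulated comparison and none of the unchanged lists was. Simulated genes were drawn independently and lists at random, so this does not measure false calls of lists whose genes vary together. For ribosomal proteins the estimated correlation was 0.916 with 644 against control.

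Alternatives were DESeq2 1.42.0, RLE normalization, library sizes alone, no low-count filter, a filter of 1 CPM in 3 samples, fits with only the 2 groups compared, the replicate number as a block, limma 3.58.1 trend tests on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library. The value given for Slc22a17, which the filter left out, is from the fit with no low-count filter. Offsets for GC content and transcript length, from GENCODE transcripts of GRCm38 for 96.4% of the genes in the table, were chosen after seeing the data. Words of 7 bases in 3' UTRs were tested by regression on UTR length, GC content and expression over 11406 genes, leaving out Nus1.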

Results

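The series measured mRNA in BV2 cells, an immortalised mouse microglial line, 48 h after the start of siRNA transfection. It had 9 libraries in 3 groups of 3 biological replicates. One group received a control, and the others received 1 of 2 siRNAs against Nus1, called 644 and 878. Nus1 encodes a subunit of the cis-prenyltransferase that makes the dolichol backbone used in protein N-glycosylation. The libraries held 19362486 to 20224998 estimated counts over 16399 genes, and 11740 genes had enough counts to be tested. The replicates were stated to be biological, but the labels do not say whether they came from separate transfections, so p-values measure only the spread between these samples.

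Nus1 was low in each knockdown library. Its level in CPM, the estimated count scaled to the library's TMM-adjusted total, was 51.6 ± 1.66 (SD, n = 3) in control, 3.85 ± 0.351 (n = 3) with siRNA 644 and 6.70 ± 2.58 (n = 3) with siRNA 878. These means were 7.46% and 13% of control. Nus1 fell by 3.74 on the log2 scale with 644 (SE 0.264, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.11e-05) and fell by 2.94 with 878 (SE 0.251, adjusted p = 6.43e-05). The 878 libraries were uneven, at 8.01, 3.73 and 8.35 CPM in replicates 1, 2 and 3. The difference in Nus1 between the siRNAs was 0.80 on the log2 scale and did not pass the test (adjusted p = 0.180), but it passed without 878 replicate 2 (1.10, adjusted p = 0.00112). Nus1 (NCBI gene 52014) lies on chromosome 10 from 52417547 to 52440192 in the deposited coordinates.

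The series title names Lcn2, a secreted siderophore-binding protein, and Slc22a17, its receptor. Lcn2 (gene 16819, chromosome 2, 32384637 to 32387739) rose from 0.273 ± 0.180 CPM (SD, n = 3) in control to 29.1 ± 1.54 with 644 and 17.8 ± 3.34 with 878. Its log2 fold change was 6.70 with 644 (SE 0.290, adjusted p = 1.54e-06, edgeR) and 5.99 with 878 (SE 0.292, adjusted p = 3.38e-06). The control libraries held 3 to 10 counts of Lcn2, so the size of the fold rests on few reads: without control replicate 1 it was 7.36 with 644 and 6.66 with 878. Slc22a17 (gene 59049, chromosome 14, 54906727 to 54913132) had 2 to 16 counts per library and was below the count filter. With no filter its log2 fold change was 1.38 with 644 (SE 0.679, adjusted p = 0.193, edgeR) and 0.61 with 878 (SE 0.743, adjusted p = 0.615), and neither passed. Without 644 replicate 2, which had 3 counts against 16 and 11 in the other 644 libraries, Slc22a17 passed the filter and the test with 644 (1.83, adjusted p = 0.0444), so at this depth the result turned on 1 library.

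**Figure D1:**
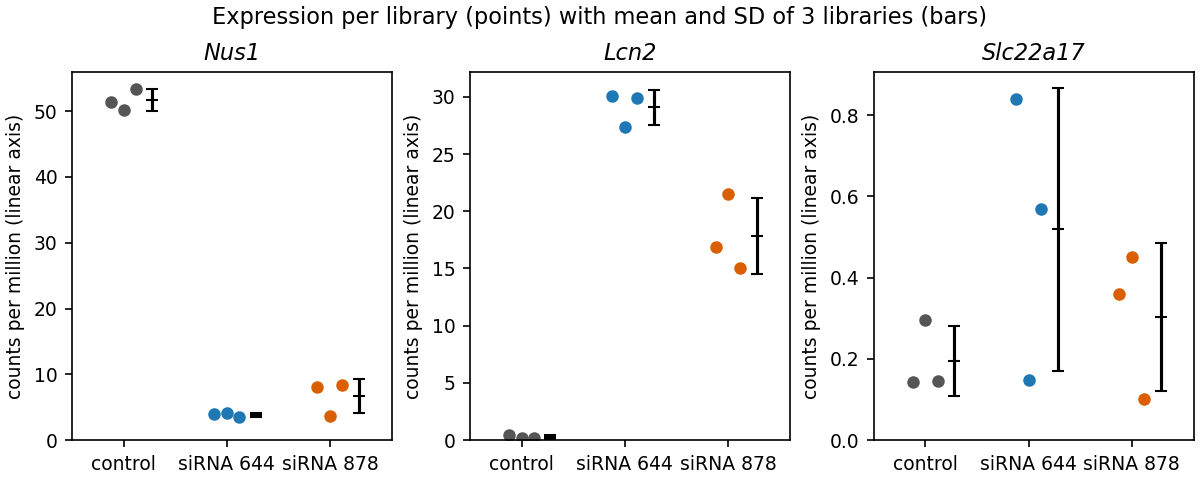
CPM of Nus1, Lcn2 and Slc22a17 on linear axes, 1 point per library, with bars for the mean and SD of the 3 libraries of each group. Nus1 was at 50.1 to 53.4 CPM in control and at 3.46 to 8.35 CPM in the knockdown libraries, and Lcn2 was below 0.5 CPM in each control library.

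The first comparison asks which genes respond to siRNA 644. Genes of the endoplasmic reticulum (ER) stress response rose, among them the chaperone Hspa5, which went from 687 ± 46.2 to 4643 ± 151 CPM (SD, n = 3 each). Ddit3, a stress-induced transcription factor, rose from 18.8 ± 2.99 to 299.9 ± 46.2 CPM. Interferon-induced and mitotic genes fell, and Cx3cr1, a chemokine receptor of microglia, fell from 24.8 ± 2.05 to 3.93 ± 0.343 CPM. In all, 1951 genes rose and 1759 fell (3710 of 11740, edgeR, adjusted p under 0.05), and 778 of these changed by at least 2-fold. The count was 6004 without 878 replicate 2, 2343 without control replicate 1 and 2379 without 644 replicate 3. With offsets for GC content and transcript length, an alternative chosen after seeing the data, 2522 rose and 2996 fell.

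Among ER chaperones and unfolded protein response genes, 20 of 26 tested members rose with 644 and none fell (median log2 fold change 1.59, camera adjusted p = 4.90e-56). The count adjusted over the list alone was 21. Herpud1 rose by 2.93 (SE 0.0796), Hspa5 by 2.76 (SE 0.0996), Creld2 by 2.71 (SE 0.114) and Hyou1 by 2.43 (SE 0.0881). Of 25 targets of the integrated stress response, which ATF4 drives, 21 rose and 1 fell (median 1.17, adjusted p = 7.12e-24; adjusted over the list alone, 22 rose and 2 fell). The pseudokinase Trib3 rose by 3.24, Ppp1r15a by 2.77 and Atf5 by 2.65. Of 42 genes of dolichol synthesis and N-glycosylation, 25 rose and none fell (median 0.43, adjusted p = 3.69e-07; adjusted over the list alone, 27 rose and 1 fell). The mannosyltransferase Alg12 rose from 11.2 ± 0.593 to 31.6 ± 0.965 CPM (SD, n = 3), Alg2 rose by 1.40, Alg5 by 1.13 and Ostc by 1.02. With an estimated correlation these 3 lists had adjusted p = 4.05e-05, 0.00877 and 0.0287.

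The iron list was also called higher with 644 (adjusted p = 0.00263; adjusted p = 0.0287 with an estimated correlation), but only 8 of 27 members rose and 1 fell, and the median was 0.13 (adjusted over the list alone, 9 and 1). Lcn2 and the ferroxidase Cp, which rose by 4.38 (SE 0.164), were far above the next members, Slc39a14 at 0.84 and Slc48a1 at 0.65. Of 42 lysosome genes, 16 rose and 4 fell (median 0.16; adjusted over the list alone, 18 and 6), with Sqstm1 at 1.97, Npc1 at 1.30, Cln3 at 1.20 and Ctsd at 0.88. The camera adjusted p was 0.00327, and adjusted p = 0.170 with an estimated correlation. Of 41 cytosolic ribosomal protein genes, 3 rose, Rplp1, Rps20 and Rps6, and the median was 0.44 (adjusted p = 0.00162; adjusted p = 0.733 with an estimated correlation; adjusted over the list alone, 0 rose and 0 fell, against 3 over all genes). The calls of Rplp1, Rps20, Rps6, Slc39a14, Ect2 and Tubb3 with 644 were lost when 644 replicate 1 or 644 replicate 3 was left out (adjusted p from 0.0510 to 0.106).

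With 644, each of the 30 tested genes of G2 and mitosis fell, also adjusted over the list alone (median -1.11, camera adjusted p = 1.91e-33). Ect2 was at -1.72, Hmmr at -1.46, Bub1 at -1.46 and Cenpf at -1.39. Of 30 S phase genes, 19 fell and none rose (median -0.51, adjusted p = 6.44e-08; 19 adjusted over the list alone), including Rrm1 at -1.24 and Lig1 at -0.86. Of 37 type I interferon response genes, 35 fell and none rose (median -1.12, adjusted p = 1.53e-22; 35 adjusted over the list alone). Ifi44 was at -3.00, Gbp3 at -2.36, Oasl2 at -1.85 and Rsad2 at -1.80, and Ifi44 was at -3.70 without 644 replicate 3. With an estimated correlation these lists had adjusted p = 0.00074, 0.00933 and 0.00537. Of 28 genes of glycolysis and the hypoxia response, 15 fell and 2 rose, also adjusted over the list alone (median -0.49, adjusted p = 1.44e-05; adjusted p = 0.0810 with an estimated correlation). Ankrd37 and Bnip3 were at -2.58 and -2.41, while Ndrg1 rose by 1.36. Of 23 cholesterol biosynthesis and uptake genes, 9 fell and none rose (median -0.38, adjusted p = 0.000614; adjusted p = 0.0238 with an estimated correlation; adjusted over the list alone, 10 fell and 1 rose). Idi1, Acat2, Pmvk and Nsdhl were at -1.30, -1.28, -1.07 and -0.94.

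The other 8 lists were not called with 644 (camera adjusted p between 0.120 and 0.986). Homeostatic microglia markers had 4 of 23 members higher and 7 lower (adjusted over the list alone, 5 and 7), with Cx3cr1 at -2.65. Disease-associated markers had 8 of 29 higher and 7 lower (8 and 8 over the list alone), with Axl at -1.44. NF-kB and cytokine genes had 5 of 28 higher and 8 lower (6 and 8 over the list alone): Il6 rose by 3.36, from 1 to 2 counts per control library, and Il1b was at -3.93, with 1 to 2 counts per 644 library. The list of NRF2 targets and ferroptosis genes had 6 of 30 higher and 4 lower (7 and 4 over the list alone), with Alox15 at 2.55. The p53 targets had 4 of 23 higher and 5 lower (5 and 6 over the list alone), with Gdf15 at 1.68. Cholesterol efflux genes had 2 of 10 higher and 1 lower, also over the list alone. Nuclear-encoded oxidative phosphorylation genes had 1 of 36 higher and 3 lower (0 and 2 over the list alone), and of 5 tested markers of other cell types 1, Tubb3, rose (0 over the list alone). The median of NRF2 and ferroptosis genes lay below 0 and their mean above it, and the p53 list had a positive median and mean with a downward test.

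The second comparison asks the same of siRNA 878. Hspa5 rose to 4348 ± 325 CPM and Ddit3 to 247 ± 76.2, and Cx3cr1 fell to 3.10 ± 0.0619 (SD, n = 3). Genes of ER stress rose and interferon-induced and mitotic genes fell. In all, 1882 genes rose and 1815 fell (3697 of 11740, edgeR, adjusted p under 0.05), and 787 changed by at least 2-fold. Without control replicate 1 the count was 2455, and it was 5631 with offsets for GC content and transcript length. With library sizes alone 1606 rose and 2138 fell, and with log2(FPKM + 1) 1585 rose and 2260 fell.

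With 878, 21 of 26 ER chaperone genes rose and none fell (median 1.64, camera adjusted p = 5.26e-59; 24 adjusted over the list alone), with Creld2 at 2.68, Hspa5 at 2.66 and Herpud1 at 2.52. Of 25 integrated stress response targets 19 rose and 1 fell (median 0.97, adjusted p = 1.69e-20; 21 and 1 adjusted over the list alone), with Ddit3 at 3.72 and Trib3 at 3.10. Of 42 dolichol and N-glycosylation genes 25 rose and none fell (median 0.48, adjusted p = 6.25e-10; 28 and 1 adjusted over the list alone), with Alg12 at 1.59 and Alg2 at 1.21. With an estimated correlation the 3 lists had adjusted p = 3.29e-05, 0.0132 and 0.0180. All 30 G2 and mitosis genes fell (median -0.95, adjusted p = 8.75e-30), as did 17 of 30 S phase genes (median -0.48, adjusted p = 7.95e-06) and 32 of 37 interferon genes (median -1.01, adjusted p = 2.36e-21), with none higher. The counts adjusted over the list alone were 30, 17 and 33. With an estimated correlation they had adjusted p = 0.00118, 0.0180 and 0.0099. Ifi44 was at -2.48, Irf7 at -2.03 and Cenpf at -1.43.

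Of 28 NF-kB and cytokine genes, 15 fell and 4 rose with 878, also adjusted over the list alone (median -0.53, adjusted p = 0.00248; adjusted p = 0.0312 with an estimated correlation). Traf1 was at -2.13 and Il1b at -2.29, while Il6 rose by 3.52 and Cd40 by 2.07. Reads were few for 3 of these: the 878 libraries held 1 to 5 counts of Traf1 and 0 to 12 of Il1b, which was at -5.10 without 878 replicate 3, and the control libraries held 1 to 2 of Il6. Of 42 lysosome genes 17 rose and 4 fell, also adjusted over the list alone (median 0.19, adjusted p = 0.00222; adjusted p = 0.142 with an estimated correlation). Of 28 glycolysis and hypoxia genes 14 fell and 2 rose (median -0.48, adjusted p = 0.00033; adjusted p = 0.141 with an estimated correlation; 16 and 2 adjusted over the list alone). Of 41 ribosomal protein genes 2 rose, Rplp1 and Rpl23 (median 0.45, adjusted p = 0.00127; adjusted p = 0.717 with an estimated correlation; 0 adjusted over the list alone). In the list of iron uptake, storage and export 4 of 27 rose and 2 fell (median 0.10, adjusted p = 0.0388; adjusted p = 0.102 with an estimated correlation; 4 and 1 adjusted over the list alone), and Cp rose from 0.709 ± 0.114 to 6.58 ± 0.835 CPM (SD, n = 3) and the iron transporter Slc11a2 by 0.72. The iron call was lost with library sizes alone (camera adjusted p = 0.179), no low-count filter (0.0889), the replicate block (0.0789) or GC and length offsets (0.0665). It was also lost without any 1 library other than 878 replicate 3 (0.0564 to 0.0954), and the ribosomal call without 878 replicate 2 (0.0732).

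The other 8 lists were not called with 878 (adjusted p between 0.206 and 0.885). They included cholesterol biosynthesis and uptake, with 6 of 23 members higher and 4 lower (7 and 4 adjusted over the list alone). Homeostatic markers had 2 of 23 higher and 6 lower, also over the list alone, with Cx3cr1 at -3.00 and Mef2c at -1.47. Disease-associated markers had 7 of 29 higher and 9 lower (7 and 10 over the list alone), with Axl at -1.78. NRF2 and ferroptosis genes had 4 of 30 higher and 4 lower and p53 targets 4 of 23 and 6, also over the list alone. Cholesterol efflux genes had 1 of 10 higher (0 over the list alone) and oxidative phosphorylation genes 2 of 36 lower (1 over the list alone). Of 5 tested markers of other cell types 3 fell, also over the list alone, among them Pecam1 at -1.47 and Cspg4 at -1.18, with 2 to 6 and 7 to 10 counts per 878 library. NRF2 and ferroptosis genes had a median of -0.05 and a mean of 0.03 with a downward test, and homeostatic markers a median of 0.03 and a mean of -0.17. The calls of Rpl23, Il1b, Pecam1 and Cspg4 with 878 were lost without 878 replicate 1 (adjusted p from 0.0554 to 0.0994), and each of these and Rplp1 without at least 1 control library.

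**Figure D2:**
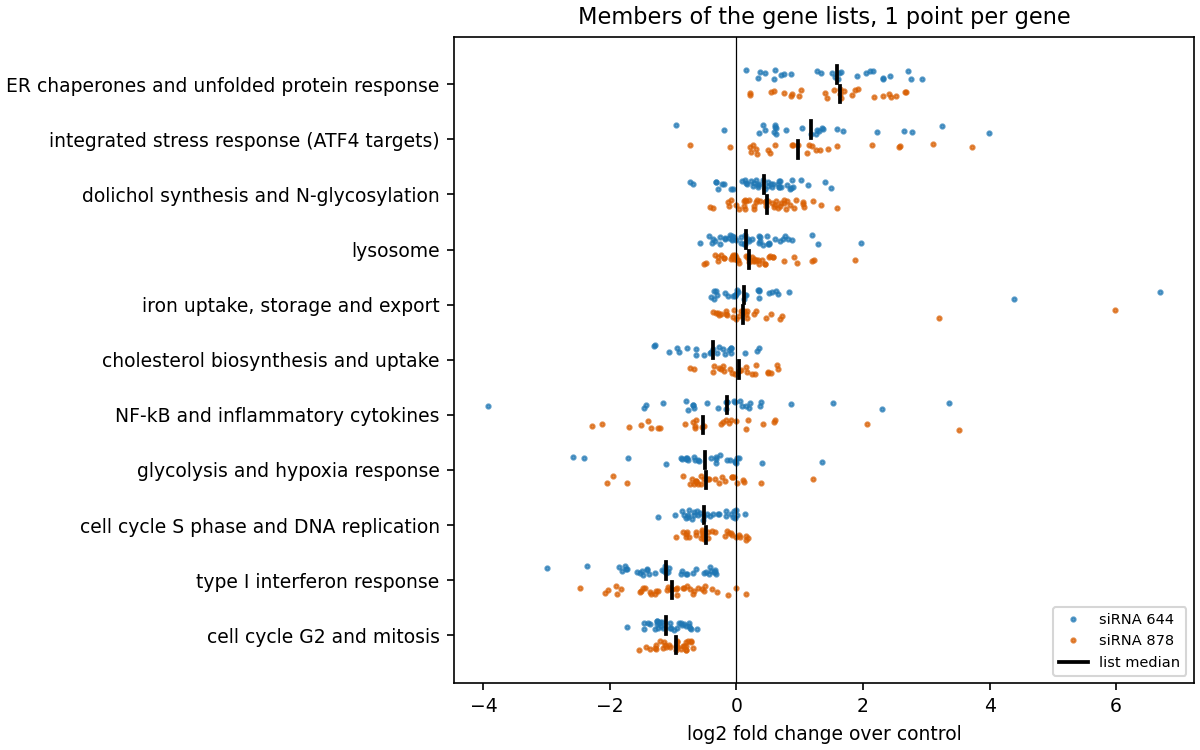
Log2 fold change over control of each tested member of 11 gene lists, 1 point per gene and siRNA, with a vertical bar at the list median. The median of the G2 and mitosis list was -1.11 with 644 and -0.95 with 878, and that of the ER chaperone list 1.59 and 1.64.

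Among genes called with both siRNAs and passing the expression minimum for named genes, those with the largest rise were Avil, Taf7l, Car6, Bglap2, Akr1b7, Lcn2, Col4a1, Angptl6, Atp2a3 and Cyp2ab1. Avil, which encodes an actin-binding protein, had 2 counts over the 3 control libraries against 9646 with 644 and 5349 with 878. The ratio of CPM was 5097 with 644 (exact 95% interval 1411 to 42090, counting error only) and 2905 with 878 (803.8 to 24000). Taf7l had 0 counts in control and was at least 93-fold higher with 644 and at least 62.6-fold higher with 878, against 3 counts over the control group. Col4a1, a basement membrane collagen, rose by 5.24 and 4.69, and Atp2a3, an ER calcium pump, by 4.60 and 3.97. By the same rule, those with the largest fall were Tnfrsf9, Nus1, Hes7, Cx3cr1, Kctd12b, Apold1, Prrg4, Ccl12, Cytip and Selenbp1. Tnfrsf9, a co-stimulatory receptor, went from 59.2 ± 5.49 to 4.65 ± 0.827 and 4.54 ± 2.34 CPM (SD, n = 3).

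In all, 1427 genes rose with both siRNAs and 1289 fell with both (2716 in the same direction), and 10 changed in opposite directions. Independent lists of these sizes would share 313 higher and 272 lower genes. In 20 simulations of unchanged groups that shared a redrawn set of controls, tested with edgeR, 0 genes were shared. At an unadjusted p under 0.05 a mean of 131.4 were shared, against 3776 observed. With no effect simulated, an adjusted test calls few genes, so the 0 says little. Simulated genes were drawn independently, so variation common to many genes is missing from all simulated values. The log2 fold changes correlated across genes, which are not independent replicates, at r = 0.887, against 0.503 in the simulations. Their covariance was 0.392 against 0.0324 simulated. The 3 control libraries could not be split into sets of at least 2, so part of the excess may come from the shared controls. Without 878 replicate 2, r was 0.801. The same-direction count was 1719 without control replicate 1 and 1779 without control replicate 3, and 4188 with GC and length offsets. The 10 genes with opposite signs, listed after their values were seen, rose with 644 and fell with 878 (4 to 55 genes with 1 library left out): Cd109, Dusp1, Farp1, H2-Q4, Mxra8, Pcx, Rab22a, Shtn1, Slc39a4 and Xdh.

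**Figure D3:**
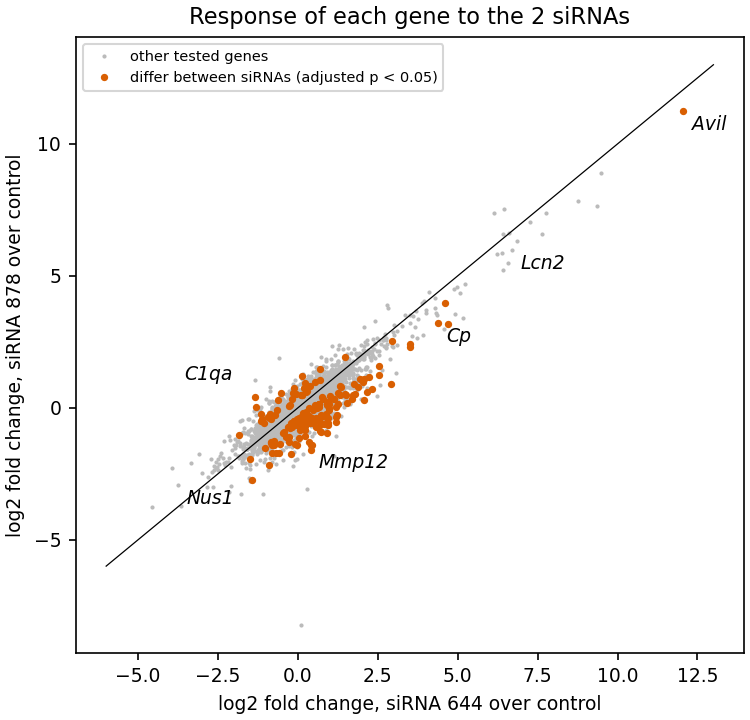
Log2 fold change of each of 11740 tested genes over control, siRNA 644 on the horizontal axis and 878 on the vertical axis, with the line of equal change. The 177 genes that differed between the siRNAs are in colour, and r across genes was 0.887.

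The third comparison asks where the siRNAs differ. P2rx3, an ATP-gated channel, was lower with 878 (27.2 ± 2.93 CPM) than with 644 (78.4 ± 3.36 CPM; SD, n = 3 each), a log2 difference of -1.53 (SE 0.121, edgeR adjusted p = 0.00217). Cp was lower by 1.18 (log2 difference -1.18, SE 0.129, adjusted p = 0.00518) and Il1rn, an interleukin 1 receptor antagonist, was at -1.02 (SE 0.112, adjusted p = 0.00518). C1qa, a complement component, was higher with 878, at 11.8 ± 2.70 against 3.49 ± 0.810 CPM (log2 difference 1.75, SE 0.227, adjusted p = 0.011). In all, 37 genes were higher and 140 lower with 878. This number depended on the fit: it was 5 with only the 2 groups compared, 688 with DESeq2 and 2071 without 878 replicate 2, and it lay between 12 and 100 without any 1 of the other libraries. DESeq2 found 274 higher and 414 lower, and GC and length offsets 829 higher and 597 lower. The calls of Cp, Il1rn and C1qa were lost without 878 replicate 1 (adjusted p = 0.0502 each) and that of C1qa also without 644 replicate 2 (0.0621) or 644 replicate 3 (0.0842).

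Of 23 cholesterol biosynthesis and uptake genes, 4 were higher with 878 than with 644 and none lower (median 0.41, camera adjusted p = 3.51e-16; adjusted p = 0.00161 with an estimated correlation; 11 and 0 adjusted over the list alone). Among them, Idi1, Nsdhl and Lss differed by 1.35, 0.59 and 0.58. Of 28 NF-kB and cytokine genes 4 were lower, Saa3, Il1rn, Nfkbia and Tlr2, and none higher (median -0.27, adjusted p = 1.04e-06; adjusted p = 0.00928 with an estimated correlation; 10 lower and 1 higher adjusted over the list alone). Of 30 NRF2 and ferroptosis genes only Gsta3 was lower, at -1.31, and 4 were lower adjusted over the list alone. Their median was -0.08 (camera adjusted p = 0.0122, adjusted p = 0.101 with an estimated correlation and adjusted p = 0.0688 without 878 replicate 2). The calls of Idi1, Nsdhl, Lss, Saa3, Tlr2 and Gsta3 were each lost without 644 replicate 1, 644 replicate 3 or 878 replicate 1 (adjusted p from 0.0618 to 0.145), and that of Nfkbia held in each of these fits. The other 16 lists were not called (adjusted p between 0.0547 and 0.852). For homeostatic markers, disease-associated markers and lysosome genes the median and the mean had opposite signs. Lcn2 did not pass the test (log2 difference -0.71, SE 0.186, adjusted p = 0.104), though it did without 878 replicate 2 (adjusted p = 0.00668) and with DESeq2 (adjusted p = 0.00207).

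With the siRNAs averaged against control, 2238 genes rose and 2174 fell (4412 of 11740), against 2017 and 2476 with library sizes alone. Nus1 was at -3.34 (SE 0.200, edgeR adjusted p = 6.13e-06) and Lcn2 at 6.34 (SE 0.279, adjusted p = 1.45e-06). The called lists were those of 878, with medians of 1.63 for ER chaperones, 1.12 for the integrated stress response, 0.46 for dolichol and N-glycosylation, -1.09 for interferon response and -1.06 for G2 and mitosis. Iron, lysosome, NF-kB, glycolysis and hypoxia, and ribosomal protein lists had adjusted p = 0.0597, 0.145, 0.0996, 0.0974 and 0.662 with an estimated correlation. The NF-kB call was lost without 878 replicate 2 (adjusted p = 0.0814), and NRF2 and ferroptosis genes, not called, had a median of -0.08 and a mean of 0.12. The count was 2869 without control replicate 1 and 2912 without control replicate 3.

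Libraries also differed within groups. The first principal component of log2 CPM (55.6% of variance) separated control from knockdown, and the second (21.8%) ran within groups, with 878 replicate 2 at 28.9 and 878 replicates 1 and 3 at -21.3 and -33.4. The 644 and control libraries lay between -16.6 and 20.1. On the third component (9.67%) the siRNAs parted, with 644 libraries at 13.5 to 17.21, 878 libraries at -21.35 to -12.02 and controls at -1.216 to 1.593. Replicates of 1 group correlated at 0.965 to 0.994 across genes, and no pair agreed within counting noise (chi-square per degree of freedom 3.47 to 114).

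**Figure D4:**
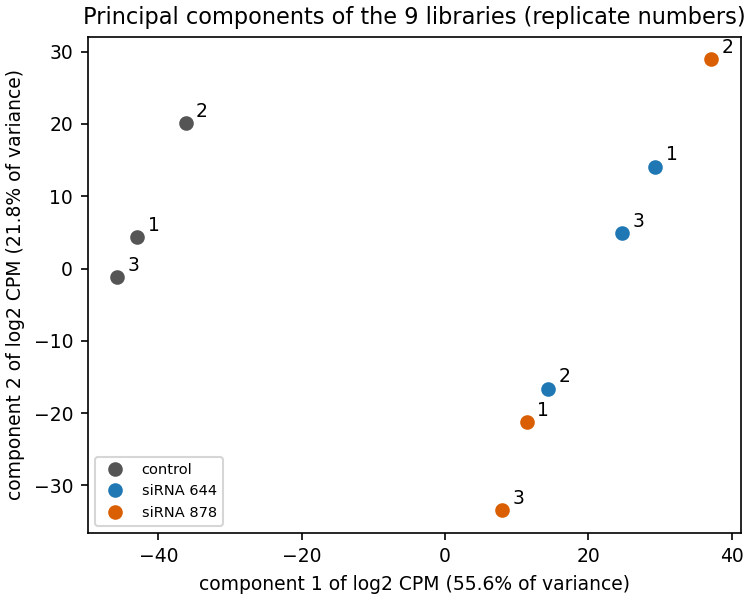
First and second principal components of log2 CPM over 11740 genes, 1 point per library, with replicate numbers. Component 1 held 55.6% of the variance and component 2 held 21.8%, with 878 replicate 2 at 28.9 on component 2.

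In the authors' deposited table, 5204 genes passed an adjusted p under 0.05 with 644 and 3138 with 878, and between the siRNAs 81 were higher and 175 lower with 878. Its log2 fold changes correlated with those computed here at 0.999 for 644, 0.983 for 878 and 0.999 for 878 against 644, across genes. The authors' deposited table gave Nus1 -3.76 and -2.95, Lcn2 6.72 and 6.02, and Slc22a17 1.41 and 0.63, with adjusted p = 0.222 and 0.790 for Slc22a17. For 644 and 878 fitted as separate pairs, edgeR here called 5543 and 2730 genes.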

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

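The tests of the sense strand of siRNA 878, of words against control, of variation shared with control libraries and of splits for genes changed in opposite directions were chosen only after the result was seen, as were the GC and length offsets.

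Effects of the 2 siRNAs against the same controls differed, by the test of 878 against 644, for 24 of the named genes reported here and 3 lists. Some of these genes were named because they were called in this same test, so the number 24 tests nothing. Log2 differences below 0 were P2rx3 -1.53, Saa3 -1.34, Apol9a -1.33, Gsta3 -1.31, Cp -1.18, Pi16 -1.08, Il1rn -1.02, Cd5 -0.90, Avil -0.80, Nfkbia -0.79, Atp2a3 -0.62, Stt3b -0.54, Tlr2 -0.50, Plk2 -0.48, Mpeg1 -0.44, Herpud1 -0.41 and Ppt1 -0.36. Those above 0 were C1qa 1.75, Idi1 1.35, C1qc 0.91, Fabp4 0.84, Nsdhl 0.59, Lss 0.58 and Rpn1 0.34. List medians were 0.41 for cholesterol biosynthesis and uptake, -0.27 for NF-kB and cytokines and -0.0752 for NRF2 and ferroptosis genes. P2rx3 was called in 19 of 19 alternatives, Nfkbia in 18, Cp and Il1rn in 16 and C1qa in 14, while Mpeg1, Herpud1, Pi16 and Apol9a were called in 9, Rpn1 and Ppt1 in 8 and Plk2 in 5. The cholesterol and NF-kB lists were called in 17 of 17 alternatives.

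The first pattern is the set of genes that differ between the siRNAs. A weaker common response with 878 is argued against, since 33.3% of the 177 genes moved the same way against control and by less with 878. For seed matches of siRNA 644, no word of 7 bases passed for genes lower with 644 than with 878. That outcome was set beforehand as counting against them, but the leading word was near the threshold (AGTTTGA, Bonferroni adjusted p = 0.0719, regression across n = 11406 genes). It lies in the Nus1 mRNA as written only at base 3656, away from base 644. TGTTTTT passed for lower expression with 644 against control (0.0377) but also went with lower expression with 878 (unadjusted p = 0.000158). It lies in no window after base 644 on either strand. If 644 is a position, these places argue against AGTTTGA and TGTTTTT as guide strand seeds of 644. A seed effect of 644 too weak to give a passing word stays open. For genes lower with 878 than with 644, 9 of 16384 words passed, 6 of them sharing no 4 bases in a row with the leading word CCTAGCA (1.08e-11). The regressions on words treat genes as independent replicates, which they are not, so their p-values do not measure the spread between libraries. As written, none of the 9 lies within 25 bases after base 878. If 878 is a position, this argues against these words as guide strand seeds of 878. A guide strand effect too weak to give a passing word stays open. CCTAGCA itself is absent from the Nus1 mRNA as written. Its reverse complement occurs there 2 times, once from base 881, 3 bases after 878, and 0.635% of words lie in such a window on either strand, so seed pairing of the sense strand of 878 is a candidate explanation for part of these genes, if 878 is a position, but no word passed for lower expression with 878 against control (CCTAGCA unadjusted p = 0.000284, not independent of its choice, against 0.988 with 644).

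The second pattern is that 878 replicate 2 stands apart from the other 878 libraries. GC content and transcript length explained 46.6% of the variance across genes of its log2 difference from them, which fits a GC or length bias. By the same measure 878 replicates 1 and 3 had 22.45% and 41.6%, and the libraries of other groups 3.31% to 26.9%. Each difference of 878 replicates 1 and 3 was taken from a mean that holds replicate 2. These differences correlated with that of replicate 2 at -0.758 and -0.890, so their shares are not independent of it. The difference of 878 replicate 2 correlated at 0.548 with that of control replicate 2 from the other controls, a library with no knockdown. With control replicates 1 and 3 it correlated at -0.183 and -0.452, and with 644 replicates 1, 2 and 3 at 0.594, -0.686 and 0.256. Differences within a group offset one another, so mixed signs arise by construction. A stronger response to the knockdown stays open: r with the effect of 644 was 0.273, and Nus1 was at 3.73 CPM in this library against 8.01 and 8.35.

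The third pattern is the higher median of ribosomal protein genes. With GC and length offsets the median, siRNAs averaged, went from 0.45 to 0.31, so a GC or length bias could account for part of it and cannot be told apart from a change in these transcripts, as the remaining value lies between the bounds set beforehand.

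Other splits of the libraries were counted. With 3 against 3 there are 10 splits, too few for a share under 0.05. For 644 against control 1 split, the real one, gave 3710 genes or 778 changed at least 2-fold, and the highest other gave 0 (edgeR; 21 to 252 genes at an unadjusted p under 0.05, against 5066). For 878 against control 1 split gave 3697 or 787, and the highest other gave 0 (35 to 1553 unadjusted, against 4997). For 878 against 644, 2 splits gave at least 177 genes: the other, with 644 replicates 1 and 3 and 878 replicate 2 on 1 side, gave 4280, which points to a structure of these samples other than the siRNA. This split follows GC content. The log2 differences of 644 replicates 1 and 3 and 878 replicate 2 from their group correlated with it at 0.393, 0.167 and 0.606. Those of 644 replicate 2 and 878 replicates 1 and 3 did so at -0.450, -0.419 and -0.573. What underlies this was not tested. For the averaged comparison, 1 of 84 splits, the real one, gave 4056 genes in a fit of 2 groups. That share is under 0.05, so chance can be excluded only as far as the libraries are interchangeable. The highest other, again with 644 replicates 1 and 3 and 878 replicate 2 on 1 side, gave 3199, so a structure other than the knockdown can also give a large count. For the same-direction genes, 1 of 100 drawn of 840 splits, the real one, gave 2716 and the highest other 2690. That share is under 0.05, but 3 others, each with the 3 controls as 1 group, gave 2279 to 2690. The share therefore speaks only for the parting of controls from knockdown libraries. It does not bear on how the knockdown libraries part, and leaves chance open for the agreement of the 2 siRNAs. For opposite directions only 4 of the 100 called any gene for both comparisons, too few for a share under 0.05: 2 of these 4 gave at least 10 genes, the real split 10 and the highest other 227.

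Counts of called lists were less specific. As many lists were called in 2 of 10 splits for 644 (11, highest other 11), in 1 of 10 for 878 (11, highest other 10) and in 9 of 10 for 878 against 644 (3, highest other 8), with too few splits for a share under 0.05. For the averaged comparison 33 of 84 splits called at least 9 lists, the highest other 12. The other splits that called as many kept part of the contrast between control and knockdown. Their group of 3 held 2 controls and 1 knockdown library, or only knockdown libraries. Splits with 1 control and 2 knockdown libraries in that group called at most 7. The number of lists therefore cannot decide on chance, which is not excluded. Each other split of 3 against 3 leaves the groups 2 to 1 on each side, so it keeps part of the real effect.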

How the results depend on the processing

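GC and length offsets were chosen only after the result was seen. Nus1 and Lcn2 had the same direction and call against control in each of 19 alternatives for 644 and 878. The balance of higher and lower genes turned with the setting: for 878 against 644 it went from 37 and 140 to 829 and 597 with offsets, and for 644 from 1951 and 1759 to 2522 and 2996. Except where fewer samples or groups were fitted, the cause of a change was not tested. The averaged comparison had no fit with only the 2 groups compared.

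For 878 against 644, where 177 genes differed, DESeq2 gave 688, library sizes alone 298, only the 2 groups compared 5, log2(FPKM + 1) 370, log2(FPKM + 0.1) 323 and GC and length offsets 1426. Genes with opposite directions went from 10 to 16 with DESeq2, 17 with library sizes alone, 20 with log2(FPKM + 1), 16 with log2(FPKM + 0.1) and 51 with offsets. Offsets gave 5631 genes for 878 against control and 4188 in the same direction with both siRNAs. The correlation across genes was 0.652 with no low-count filter. Genes changed at least 2-fold numbered 381 for 644 and 364 for 878 with log2(FPKM + 1), where the pseudocount shrinks the change of low genes. Lists called for 878 against 644 went from 3 to 7 with library sizes alone, 5 with no low-count filter and 7 with fry. An estimated correlation gave 7 lists for 878 and 6 for the averaged comparison.

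Leaving out 1 library at a time gave 2343 to 6004 genes for 644, 2455 to 4825 for 878, 12 to 2071 for 878 against 644 and 2869 to 5878 averaged. It gave 683 to 858 and 696 to 895 genes changed at least 2-fold for 644 and 878, 1719 to 3507 in the same direction and 4 to 55 in opposite directions. The correlation was 0.801 to 0.890, and Nus1 was at -3.80 to -3.67 with 644 and at -3.13 to -2.65 with 878. Lists called were 11 to 11 for 644, 9 to 11 for 878, 3 to 9 for 878 against 644 and 10 to 11 averaged. Among named genes and the lists called with all libraries in, 284 calls were lost over all such fits and 3 were gained. Lists not called with all libraries in were left out of this count, so it holds no gained list call.

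No pairing of the samples by replicate number was seen. Deviations of same-numbered libraries from their group means correlated at -0.686 to 0.548 across genes, with 2 of 9 pairs over 0.1, and 1 of 9 libraries correlated best with its own number. These deviations also carried the trend with GC content and transcript length, which could hide a smaller effect shared by replicate number. With the replicate block, 2853 genes changed for 644, 2887 for 878, 3682 averaged and 14 between the siRNAs, and 6 went in opposite directions. Among the lists, the block ended the iron call for 878 (adjusted p = 0.0789) and added a call for markers of other cell types between the siRNAs (0.0423). At 19362486 to 20224998 counts per library, Slc22a17 had at most 16 counts, which limits what could be seen for it.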

Other observations

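The pathway tests and the counts of the word CCTAGCA were chosen only after the result was seen. The pathways came from the annotation in the deposited table (318 pathways of 10 to 300 tested genes). Of 25 protein export genes, 15 rose and none fell with the siRNAs averaged (median log2 fold change 0.49, camera adjusted p = 4.44e-07; adjusted p = 0.0908 with an estimated correlation). Of 50 genes of the Fanconi anemia pathway, which repairs DNA crosslinks, 20 fell and 2 rose (median -0.23, adjusted p = 0.011; adjusted p = 0.160 with an estimated correlation), and of 39 genes of homologous recombination 18 fell and 3 rose (median -0.25, adjusted p = 0.0411; adjusted p = 0.219 with an estimated correlation). Protein processing in the endoplasmic reticulum kept its call with an estimated correlation for the siRNAs averaged (67 of 145 rose and 10 fell, adjusted p = 0.0348) and for 878 (adjusted p = 0.0223), and lost it for 644 (adjusted p = 0.0563). Of its 145 genes, 39 are also in the gene lists fixed beforehand, so it partly repeats those results.

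The word CCTAGCA was in the 3' UTR of 29 of 138 searched genes lower with 878 than with 644 (21%), against 10.0% of all 11406 searched genes. The word was picked from these same differences, so the shares describe the set and test nothing. Among the 29 were Mmp12 at -1.98, Rab22a at -1.85 and Pirb at -1.56, chosen after their values were seen. The median log2 difference of genes with the word was -0.03, against 0.02 for the others. Against control it was -0.0460 with 878 and -0.0396 with 644, against 0.00746 and -0.00375 for the others, with no adjustment for the length or GC content of the UTR.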
